A study of Homo sapiens with 24 samples.

How the data were processed

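Gene expression was measured on 24 Affymetrix HG-U133 Plus 2.0 arrays of MCF7 cells, an established human breast cancer line that expresses estrogen receptor alpha. Per the labels, the arrays came from 2 subclones of the line, a tamoxifen-sensitive clone (B7) and a tamoxifen-resistant clone (G11OH-T). Cells were kept for 2 days in medium with 5% charcoal-dextran treated serum, which holds little steroid, and then treated for 4 hours. The 4 treatments were vehicle control, estradiol, 4-hydroxytamoxifen (4OHT, the active form of tamoxifen) at 1 micromolar, and estradiol with 4OHT, each with 3 replicates per clone. The dose of estradiol is left out because its exponent is garbled in the labels. The labels do not say whether replicates were separate cultures, so every p-value given here measures only the spread between arrays.

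The deposited table holds 1 value per probe set and array in the unit intensity, on a linear scale, and per the labels the authors obtained it in dChip, with arrays normalized to each other by the invariant set method and background taken as the perfect match minus mismatch difference. The dChip version was not given. The deposited instrument files, 1 per array and of the unit other, hold text settings of the array run and no expression values. They were used only to read the fluidics station and a coded operator of each array as possible batches. The table lists 54675 probe sets, of which 62 control probe sets were left out. Of all values, 1.15% were exactly 1, and 0 to 4 values of an array lay below 1. All columns were mapped to a sample and none were identical. No counts or reads exist for arrays, so the number of arrays limits the precision.

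Values below 1 were set to 1, and log2(value + 32) was taken. A probe set was kept when its value lay above the median of all values, 16.9, in at least 3 of the 24 arrays, which left 35191 probe sets. R 4.3.3 and limma 3.58.1 were used. One linear model with a mean for each of the 8 groups was fitted to all 24 arrays, with eBayes moderation and an intensity trend, and 13 comparisons were taken from it. These were estradiol against control, 4OHT against control, 4OHT on top of estradiol and estradiol on top of 4OHT in each clone, the 4 differences of these effects between the clones (resistant minus sensitive), and resistant against sensitive control. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 over all probe sets tested in that comparison. Changes are differences of log2(value + 32), which understates the fold of weakly expressed genes, so that no folds are given. They stand with the model's standard error (SE), and group levels as mean and SD of 3 arrays.

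Genes were named from probe sets that the platform annotation pairs with exactly 1 symbol: 28329 probe sets and 15575 genes among those tested. The probe set with the highest mean stood for a gene, with cross-hybridizing _x_at probe sets only where no other existed. The annotation gives a chromosome and a gene identifier, and no coordinates on a build were used. For each comparison the named genes were the 6 largest rises and the 6 largest falls that were called and whose 3 arrays in one group all lay above the 3 in the other. For clone differences these were 5 and 5 with no condition on overlap. Up to 2 called members of each gene list with the smallest adjusted p were added, as were 8 index genes in every comparison whatever their test: ESR1, PGR, GREB1, TFF1, MYC, CCND1, CXCL12 and HSPB8. HSPB8 was taken as known from the study on this screen, the others as classical estrogen receptor or estrogen-responsive genes. Further members of a called list could be named as its examples.

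A set of 20 gene lists was written from textbook knowledge, with 336 genes of which 287 were measured: estrogen-induced, estrogen-repressed, immediate-early, G1/S and replication, mitosis, ribosome biogenesis, sterol synthesis, unfolded protein response, heat shock, autophagy, interferon, growth factor signalling, estrogen receptor coregulators, luminal markers, basal and mesenchymal markers, hypoxia, aryl hydrocarbon receptor targets, and fibroblast, leukocyte and endothelial markers. Lists were tested with limma camera, which compares a list with all other genes, at a preset correlation of 0.01 between genes. The camera test with an estimated correlation and fry, which tests whether the genes of a list move one way on balance, were run beside it. Adjusted p-values of lists are over the 20 lists of a comparison. Called members were counted after adjustment over all probe sets and also adjusted over the list alone.

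An estrogen response score was computed for each array as the mean log2 value of the probe sets called higher for estradiol in the other clone minus the mean of those called lower there, so that the changes used for selection came from arrays that were not scored. The variance behind the selection came from the model of all 24 arrays. The clone difference of the score, planned before the data were examined, is not given, since the clones are scored on different probe sets. Score differences were tested with a two-sided exact permutation test, which cannot go below 0.1 with 3 arrays against 3. Agreement between responses was described by correlations across probe sets, which are not independent replicates. The 2 responses that share control arrays were compared with the mean of 50 simulations with no effect.

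The lists, the comparisons, the rule for named genes and all alternatives but 1 were chosen before the data were examined. The alternatives were pseudocounts of 8 and 100, no filter, a filter at the 75th percentile, quantile normalization, a model of only the groups compared, a block for the replicate number, the station as a fixed or a random block, the mean of all probe sets of a gene, the study's own criterion of a 90% confidence interval beyond 1.1-fold, and leaving out each array in turn. Leaving out 3 sensitive arrays together (control 3, estradiol 3 and 4OHT 1) was chosen after seeing the data. A replicate block was not part of the model because the replicate numbers gave no sign of pairing arrays: of 36 same-number pairs of arrays, 4 had deviations from their group means that correlated above 0.1, and only 9 of 24 arrays correlated most with their own number. Station was not part of the model because it goes with the groups and a fixed station block could be fitted for 4 of the 13 comparisons.

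The model was tested on simulated data with 200 changed probe sets. For estradiol in the resistant clone it recovered 40% of changes of 0.5 and 100% of changes of 1 (log2). For the clone difference of estradiol on top of 4OHT it recovered 15.7% and 95.2%. Of the probe sets it called, 4 (2.47%) were unchanged ones for the first and 8 (5.52%) for the second of these, 11 (7.80%) for the clone difference of estradiol and 21 (11.0%) for estradiol on top of 4OHT in the resistant clone. The last 3 shares lie above the 5% set. All of them come from a single simulated data set, which does not show whether the model exceeds 5% on average. With no change it called 0 probe sets and 0 lists. Errors were drawn independently for each probe set, so that this says nothing on lists whose genes are correlated.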

Results

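Expression was measured on 24 arrays of MCF7 breast cancer cells, with 3 arrays in each of 8 groups: a tamoxifen-sensitive and a tamoxifen-resistant clone, each as control or after 4 hours of estradiol, 4-hydroxytamoxifen (4OHT) or estradiol with 4OHT. The median value of an array ran from 16.5 to 17.5 intensity units, and the correlation of log2 values between replicates from 0.973 to 0.988. Correlations between arrays of different clones ran from 0.937 to 0.961. The log2 ratio of the 3' to the 5' GAPDH probe sets, a sign of RNA integrity, had a mean of 0.274 ± 0.112 (SD, n = 12) in the sensitive and 0.293 ± 0.0936 (SD, n = 12) in the resistant clone. It was highest in replicate 3 of sensitive estradiol with 4OHT (0.585) and replicate 1 of resistant estradiol (0.540). In the sensitive clone, 3 arrays stood apart from the other replicates of their groups in estrogen-induced genes: control 3, estradiol 3 and 4OHT 1. On a scale from control 1 and 2 (0) to estradiol 1 and 2 (1), the 26 such genes with a clear difference between these ends had medians of 0.651, 0.318 and 0.181. The last compares with 0.0826 and 0.0879 in 4OHT 2 and 3 and with 0.124 to 0.211 in the arrays with estradiol and 4OHT. TFF1 stood at 1.00 in 4OHT 1. In the estrogen response score 4OHT 1 (-0.935) lay near 4OHT 2 (-0.947) and 4OHT 3 (-0.980). It thus stood apart less clearly than control 3 and estradiol 3. Replicate 3 of estradiol with 4OHT was kept, though it correlated at 0.980 and 0.978 with its replicates (0.987 between these). Counts without the 3 arrays are given beside those of all arrays. That alternative was chosen after seeing the data, and removing arrays because they deviate lowers the spread that the test uses. Since the 3 arrays differ in estrogen-induced genes, a larger estrogen response without them follows in part from the choice.

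The steroid-depleted controls show how the clones differed before treatment. The resistant clone had higher levels of ALCAM, a cell adhesion molecule (10.03 ± 0.09 against 5.87 ± 0.28 on the scale of log2(value + 32), SD, n = 3 each, difference 4.15), LXN, a carboxypeptidase inhibitor (3.96), keratin KRT13 (3.45), SYBU (3.00), the transcription factor MYC (2.81) and the secreted glycoprotein STC2 (2.75). It had lower levels of the Wnt ligand WNT2B (5.61 ± 0.02 against 10.45 ± 0.08, SD, n = 3 each, difference -4.84), the actin regulator EVL (-4.41), interferon-induced IFI6 (-3.57), the protease inhibitor CSTA (-3.51), protocadherin PCDH10 (-3.10) and TNFRSF11B, the decoy receptor osteoprotegerin (-2.98). The levels of KRT13 and SYBU in the sensitive and of WNT2B, EVL, IFI6 and GREB1 in the resistant clone lay near or below the median of all values (16.9 intensity units), so that no exact fold can be given. The estrogen receptor gene ESR1 (gene identifier 2099, chromosome 6) was lower in the resistant clone by its strongest probe set, with a change of -1.03 on the log2 scale (SE 0.09, adjusted p = 1.72e-09). Of the 9 ESR1 probe sets, 4 were called lower and 2 had the opposite sign. Of the other index genes, GREB1 (-1.51), TFF1 (-1.68) and CCND1 (-0.73) were lower, and HSPB8 (1.56) and MYC (2.81) were higher in the resistant clone. PGR (-0.13, adjusted p = 0.631) and CXCL12 (-0.60, adjusted p = 0.068) did not pass the test. In all, limma called 6103 of 35191 probe sets, 3178 higher and 2925 lower in the resistant clone, and 6648 without the 3 arrays that stood apart (3290 higher and 3358 lower). Without sensitive control 3 alone the log2 difference was 3.62 in place of 2.81 for MYC, 3.39 in place of 2.75 for STC2, -0.79 for GREB1 and -1.20 for TFF1, and CCND1 was no longer called (-0.46, adjusted p = 0.0694).

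Camera called 6 lists between the untreated clones, none of them with an estimated correlation. Without the 3 arrays that stood apart, ribosome biogenesis (adjusted p = 0.000342), interferon and growth factor signalling (adjusted p = 0.0101 each) passed with an estimated correlation. Of 17 ribosome biogenesis genes, 13 were higher in the resistant clone and 0 lower (15 higher adjusted over the list alone), among them NCL, the major nucleolar protein (0.67), and PES1 (0.62), with a list median of 0.62 and an adjusted p of 1.14e-06 (adjusted p = 0.347 with an estimated correlation). Of 9 heat shock genes, 6 were higher and 1 lower (the same numbers adjusted over the list alone), led by the mitochondrial chaperonins HSPD1 (1.11) and HSPE1 (1.13), with an adjusted p of 0.00212 (adjusted p = 0.0637 with an estimated correlation). Of 20 mitosis genes, 8 were higher and 1 lower (11 and 2 adjusted over the list alone), among them AURKB (0.43) and CDC20 (0.38), at an adjusted p of 0.0164 (adjusted p = 0.616 with an estimated correlation, and adjusted p = 0.125 without sensitive control 1). Of 21 interferon genes, 7 were lower and 1 higher (11 and 2 adjusted over the list alone), with IFITM1 at -1.44, at an adjusted p of 0.00212 (adjusted p = 0.0637 with an estimated correlation). Of 20 growth factor signalling genes, 7 were lower and 0 higher (7 and 1 adjusted over the list alone), among them the insulin receptor substrate IRS1 (-2.02) and the GDNF receptor GFRA1 (-1.62), at an adjusted p of 0.00817 (adjusted p = 0.182 with an estimated correlation). Of 17 luminal markers, 9 were lower and 2 higher (10 and 3 adjusted over the list alone), with the luminal transcription factor GATA3 at -1.01 and AGR2 at 2.27, at an adjusted p of 0.00457 (adjusted p = 0.0637 with an estimated correlation). Stations of the resistant and sensitive controls did not overlap, so that clone and station cannot be told apart in this comparison.

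Of the remaining lists, camera called none between the untreated clones with all arrays. Without the 3 arrays that stood apart it called the estrogen-induced (15 higher and 5 lower, adjusted p = 5.57e-05), estrogen-repressed (4 higher and 9 lower, adjusted p = 0.00489), sterol synthesis (7 higher and 1 lower, adjusted p = 0.00465) and aryl hydrocarbon receptor lists (0 higher and 3 lower, adjusted p = 0.0152), none of them with an estimated correlation (adjusted p from 0.11 to 0.319). With all arrays the counts were as follows. Of 32 estrogen-induced genes 11 were higher and 4 lower (11 and 6 adjusted over the list alone, adjusted p = 0.0686), with FHL2 at 2.10 and KRT13 at 3.45. Of 18 estrogen-repressed genes 3 were higher and 7 lower (4 and 8 adjusted over the list alone, adjusted p = 0.363), with NDRG1 at 1.21 and YPEL3 at -1.70. Other genes higher in the resistant clone were XBP1, a transcription factor of the unfolded protein response (1.57), ASNS, asparagine synthetase (1.04), LDHA, lactate dehydrogenase A (0.87), the replication helicase subunit MCM4 (0.65), the sterol synthesis enzyme MSMO1 (0.84), fibronectin FN1 (0.81) and the coactivator MED1 (0.36). Lower were the mesenchymal transcription factor TWIST1 (-1.99), the aryl hydrocarbon receptor targets CYP1A1 (-1.79) and CYP1B1 (-1.42), the coactivator NCOA1 (-0.65), UNG (-0.64), GABARAPL2 (-0.64), NSDHL (-0.62), the autophagy receptor SQSTM1 (-0.56) and IER2 (-0.51). CYP1A1 stood at -2.56 without sensitive control 3 and was no longer called without sensitive control 1 (-1.36) or 2 (-1.44). The call of MSMO1 ended without sensitive control 1 (0.63), and that of MED1 without it (0.28) or resistant control 1 (0.32). Of 6 measured fibroblast markers COL1A1 was lower (-0.66) and THY1 higher (0.44, no longer called at 0.35 to 0.48 on leaving out any 1 control array but sensitive control 3), and the list was not called (adjusted p = 0.91). Lists that camera called in none of the 13 comparisons gave, between the untreated clones, 2 higher and 4 lower of 19 autophagy genes (3 and 5 adjusted over the list alone, adjusted p = 0.207), 2 higher and 1 lower of 13 hypoxia genes (4 and 4 adjusted over the list alone, adjusted p = 0.895) and 2 higher and 2 lower of 12 receptor coregulators (the same adjusted over the list alone, adjusted p = 0.908). Basal and mesenchymal markers had 1 higher and 1 lower of 11 (2 and 1 adjusted over the list alone, adjusted p = 0.919). None of 5 measured leukocyte and 4 endothelial markers was called (adjusted p = 0.989 each).

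Estradiol against control in the resistant clone asks how the resistant cells responded to estrogen. Estradiol raised IGFBP4, which binds insulin-like growth factors (gene identifier 3487, chromosome 17), from 6.33 ± 0.26 to 8.72 ± 0.16 (SD, n = 3 each), a change of 2.38 (SE 0.37, adjusted p = 0.00253). The ubiquitin ligase gene SIAH2 rose by 1.84, the adrenergic receptor ADRA2A by 1.55, the small heat shock protein HSPB8 by 1.47, the transcription factor MYBL1 by 1.39 and the potassium channel KCNK6 by 1.32. Smaller rises were those of the luminal transcription factor TFAP2C (0.59) and of TIPARP (0.59). The dihydroceramide desaturase DEGS1 fell (-0.86), as did TM4SF1 (-0.73), SYTL2 (-0.71), the apoptosis regulator PAWR (-0.61), the phosphatase PPM1H (-0.58) and PWWP3B (-0.54). In all, 70 probe sets were called, 58 higher and 12 lower. Leaving out 1 of the 6 arrays gave 16 (without control 3) to 48 (without estradiol 2). Leaving out the 3 sensitive arrays, which enter here only through the spread of the shared model, gave 305. Of the other index genes, TFF1 (1.01, adjusted p = 0.285), CCND1 (0.70, adjusted p = 0.175) and MYC (0.45, adjusted p = 0.94) did not pass the test, and PGR, GREB1, CXCL12 and ESR1 had values between -0.02 and 0.19.

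Camera called the estrogen-induced list upward in the resistant clone. Of 32 measured genes 6 were called higher and 0 lower (18 adjusted over the list alone), with a median of 0.58 and an adjusted p of 2.15e-30 (adjusted p = 0.0722 with an estimated correlation). Without the 3 sensitive arrays 18 were called and the list passed with an estimated correlation (adjusted p = 0.000857), as did ribosome biogenesis with 0 called members (adjusted p = 0.0145). Besides SIAH2, IGFBP4, MYBL1 and HSPB8, these were the retinoic acid receptor RARA (0.84) and the adenylate cyclase ADCY9 (0.73). Camera also called the unfolded protein response upward with 0 called members of 17 (2 adjusted over the list alone, median 0.14, adjusted p = 0.000891, and adjusted p = 0.0722 with an estimated correlation) and the G1/S and replication genes upward with 0 of 21 (1 adjusted over the list alone, median 0.11, adjusted p = 0.000215, and adjusted p = 0.447 with an estimated correlation). Ribosome biogenesis had a median of 0.15 with 0 of 17 called on either count (adjusted p = 0.00442, and adjusted p = 0.774 with an estimated correlation). Estrogen-repressed genes had a median of -0.12 with 0 of 18 called (1 lower adjusted over the list alone, adjusted p = 0.0103, and adjusted p = 0.691 with an estimated correlation). Within station 2, which held 2 arrays of each group, 70 of 70 called probe sets changed the same way, with a median ratio of 0.991 to their change over all arrays. These arrays are among those that gave the calls, which favours such agreement. With a fixed station block the call remained for 5 probe sets, all higher and all among the 70.

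In the sensitive clone, estradiol against control asks the same of the sensitive cells. Named rises were those of C6orf141 (7.17 ± 0.18 against 6.32 ± 0.43, SD, n = 3 each, change 0.84, SE 0.15, adjusted p = 0.026), the mitochondrial import factor TOMM34 (0.81), the endoplasmic reticulum protein SDF2L1 (0.58), the methionine sulfoxide reductase MSRB3 (0.54) and the translation initiation scaffold EIF4G1 (0.44). PRR15L fell (-0.99, SE 0.16, adjusted p = 0.0189), as did the signalling adaptor BCAR3 (-0.98), KLHDC8B (-0.72), TP53I11 (-0.70), EDDM3A (-0.68), the sialyltransferase ST6GALNAC2 (-0.60) and the dynein subunit DYNC1LI1 (-0.60). In all, 42 probe sets were called, 18 higher and 24 lower. None of the 8 index genes passed the test with all arrays: MYC had a change of 1.40 (SE 0.36, adjusted p = 0.0799) with a control SD of 1.40, HSPB8 of 1.14 (adjusted p = 0.0669), GREB1 of 0.90 (adjusted p = 0.237), CCND1 of 0.77 (adjusted p = 0.0674), TFF1 of 0.75 (adjusted p = 0.273), CXCL12 of 0.55, PGR of 0.23 and ESR1 of -0.15.

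Camera called 5 lists for estradiol in the sensitive clone, none with an estimated correlation and none with a member called over all probe sets. Of 32 estrogen-induced genes, 30 had a positive change and 0 were called over all probe sets (21 higher adjusted over the list alone), with a median of 0.69 and an adjusted p of 1.95e-18 (adjusted p = 0.301 with an estimated correlation). All 17 ribosome biogenesis genes had a positive change, 0 called (14 adjusted over the list alone), with a median of 0.39 and an adjusted p of 1.44e-11 (adjusted p = 0.301 with an estimated correlation). Examples were the ribosome assembly factors RRS1 (0.74) and NOP16 (0.75), which did not pass the test singly. Estrogen-repressed genes had a median of -0.30, 0 called and 7 lower adjusted over the list alone (adjusted p = 0.000289, and adjusted p = 0.471 with an estimated correlation). G1/S and replication genes had a median of 0.14, 0 called and 1 adjusted over the list alone (adjusted p = 0.0135, and adjusted p = 0.539 with an estimated correlation). Mitosis genes had a median of -0.13, 0 called and 1 lower adjusted over the list alone (adjusted p = 0.00542, and adjusted p = 0.539 with an estimated correlation), a call that ended without the 3 arrays that stood apart.

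Without those 3 arrays, estradiol called 1720 probe sets in the sensitive clone, 838 higher and 882 lower, including the 42 called with all arrays. MYC then rose by 2.49, IGFBP4 by 2.38, GREB1 by 1.99 and HSPB8 by 1.98, and 26 of 32 estrogen-induced genes and 14 of 17 ribosome biogenesis genes were called higher (adjusted p = 0.00053 and 2.19e-05 with an estimated correlation). The estrogen-repressed and the G1/S and replication lists then also passed with an estimated correlation (adjusted p = 0.0184 and 0.0466). Leaving out control 3 alone gave 1279 called probe sets, leaving out estradiol 1 gave 0, and a model of only the groups compared gave 0. All sensitive controls ran at 1 station under operator 1 and the other sensitive arrays at other stations under operator 2, so that treatment and batch cannot be told apart in this comparison. The test of the difference between the clones called 3 probe sets of 2 genes with all arrays, and 0 in a model of only the groups compared. Leaving out 1 array gave 3 to 40, with 40 without sensitive control 3 and 13 without sensitive estradiol 3. The difference was positive for both genes: ADRA2A (1.33, SE 0.19, adjusted p = 0.00401) and RETREG1, a receptor for autophagy of the endoplasmic reticulum (1.25, SE 0.17, adjusted p = 0.00294). The RETREG1 mean went from 6.71 to 7.64 in the resistant and from 7.46 to 7.15 in the sensitive clone. Ribosome biogenesis genes had a median clone difference of -0.23 with 0 of 17 called on either count (adjusted p = 0.000698, and adjusted p = 0.982 with an estimated correlation). Without the 3 arrays 242 probe sets differed, with GREB1 (-1.92) and MYC (-2.04) rising less in the resistant clone and 7 of 17 ribosome biogenesis genes and 11 of 32 estrogen-induced genes called lower (adjusted p = 5.79e-05 and 0.0402 with an estimated correlation).

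Across all probe sets the estradiol changes of the clones had a Pearson correlation of 0.214 and a Spearman correlation of 0.119. Of the 70 probe sets called in the resistant clone, 64 had the same sign in the sensitive clone, and of the 42 called in the sensitive clone, 36 had the same sign in the resistant clone. Shared calls were 0 higher and 1 lower. Without the 3 arrays, 201 of the 305 probe sets called in the resistant clone were also called with the same sign in the sensitive clone, where 7.39 are expected of independent lists.

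4OHT against control asks whether tamoxifen's active form acted on its own. In the sensitive clone the cytochrome P450 genes CYP1A1 (-1.60, SE 0.46, adjusted p = 0.297) and CYP1B1 (-0.92, SE 0.25, adjusted p = 0.288) had negative changes that did not pass the test. As a list, the aryl hydrocarbon receptor targets had a median of -0.32 with 0 of 7 called (4 lower adjusted over the list alone, adjusted p = 0.00119, and adjusted p = 0.245 with an estimated correlation). Limma called 0 probe sets, where 3534 had an unadjusted p under 0.05. Leaving out control 3 alone gave 16. Without the 3 arrays, 24 were called, 12 higher and 12 lower, among them CYP1A1 (-2.70) and CYP1B1 (-1.61), and the aryl hydrocarbon receptor list passed with an estimated correlation (adjusted p = 0.00206). As for estradiol, all sensitive controls ran at another station and under another operator than the 4OHT arrays, so that treatment and batch cannot be told apart here or in the clone difference. In the resistant clone 4OHT raised the antisense transcript NAV2-AS4 from 5.65 ± 0.09 to 6.58 ± 0.09 (SD, n = 3 each), a change of 0.93 (SE 0.14, adjusted p = 0.0197) and the only call, which a fixed station block and a pseudocount of 8 ended, as did leaving out any 1 of the 6 arrays but control 3. It stayed the only call without the 3 sensitive arrays. Sterol synthesis genes had a median of 0.12 there, with 0 of 15 called on either count (adjusted p = 0.0443, and adjusted p = 0.935 with an estimated correlation). The clone difference called 0 probe sets with limma, where 2679 had an unadjusted p under 0.05, and 8 without the 3 arrays. Leaving out 1 array gave 0 or 1. Its aryl hydrocarbon receptor targets had a median of 0.41 with 0 of 7 called (4 adjusted over the list alone, adjusted p = 0.00338, and adjusted p = 0.353 with an estimated correlation, or adjusted p = 0.00306 without the 3 arrays). The index genes did not pass the test in either clone: their changes ran from -0.57 for GREB1 to 0.42 for HSPB8 in the sensitive and from -0.22 for CCND1 to 0.11 for ESR1 in the resistant clone. The 4OHT and estradiol changes correlated across probe sets at 0.585 in the sensitive and 0.435 in the resistant clone, where their shared controls alone gave 0.50 in simulations.

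4OHT on top of estradiol asks which estrogen responses tamoxifen's active form blocked. In the sensitive clone 4OHT lowered GREB1, a classical estrogen receptor target, from 7.61 ± 0.65 to 5.98 ± 0.10 (SD, n = 3 each), a change of -1.63 (SE 0.34, adjusted p = 0.0481). It also lowered the immediate-early gene EGR3 (-1.30), the neuropeptide Y receptor NPY1R (-1.28), SIAH2 (-1.19), the ephrin receptor EPHA4 (-0.91), C1orf226 (-0.89) and OLFM1 (-0.86). It raised the mTORC1 inhibitor DDIT4 (1.23), PRR15L (1.15), BCAR3 (1.14), the transcription factor SOX2 (1.10), TNFRSF11B (1.00) and the metalloproteinase MMP16 (0.98). PRR15L and BCAR3 had fallen with estradiol alone, but both comparisons share the estradiol arrays with opposite sign, which favours opposite changes even with no effect. In all, 49 probe sets were called, 34 higher and 15 lower, and 13 and 10 after quantile normalization, which ended the calls of GREB1, EGR3, C1orf226, DDIT4 and TNFRSF11B. MYC (-1.59, adjusted p = 0.0638), TFF1 (-1.16, adjusted p = 0.101), CXCL12 (-0.94, adjusted p = 0.0789), HSPB8 (-0.90, adjusted p = 0.153) and CCND1 (-0.69, adjusted p = 0.109) did not pass the test, nor did PGR (-0.32) and ESR1 (0.25).

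Camera called 7 lists for 4OHT on top of estradiol in the sensitive clone. Their signs are no separate evidence beside those for estradiol alone, since the estradiol arrays are shared. Of 32 estrogen-induced genes 4 were called lower (23 adjusted over the list alone), with a median of -0.67 and an adjusted p of 1.23e-24 (adjusted p = 0.13 with an estimated correlation). Of 17 ribosome biogenesis genes 0 were called (13 lower adjusted over the list alone), with a median of -0.36 and an adjusted p of 4.04e-16 (adjusted p = 0.13 with an estimated correlation). Estrogen-repressed genes, among them TP53INP1 (1.15) and CCNG2 (1.06), had a median of 0.43 with 0 called (10 higher adjusted over the list alone, adjusted p = 1.15e-06, and adjusted p = 0.166 with an estimated correlation). G1/S and replication genes had a median of -0.20 with 0 called (2 lower adjusted over the list alone, adjusted p = 2e-05, and adjusted p = 0.198 with an estimated correlation), and mitosis genes of 0.20 with 0 called on either count (adjusted p = 0.000153, and adjusted p = 0.198 with an estimated correlation). Immediate-early genes had a median of -0.06 with EGR3 called (1 higher and 2 lower adjusted over the list alone, adjusted p = 0.027, and adjusted p = 0.296 with an estimated correlation). Aryl hydrocarbon receptor targets had a median of 0.23 with 0 called (3 adjusted over the list alone, adjusted p = 0.0129, and adjusted p = 0.198 with an estimated correlation), a call that ended without the 3 arrays. Without these, 911 probe sets were called, including the 49, and GREB1 changed by -2.01 and IGFBP4 by -1.89. With an estimated correlation the estrogen-induced (24 lower, adjusted p = 0.000256), ribosome biogenesis (12 lower, adjusted p = 2.23e-05), estrogen-repressed (adjusted p = 0.0125) and G1/S and replication lists (adjusted p = 0.0446) then passed. Leaving out estradiol 3 alone gave 364, leaving out estradiol 1 gave 0, and a fixed station block gave 5, of which 0 were among the 49. The estradiol arrays ran at station 5 and those with both compounds at stations 6 and 7, so that no station held both groups. The block therefore rests on 4OHT 1, the only 4OHT array at station 5 and 1 of the 3 that stood apart.

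In the resistant clone 4OHT on top of estradiol raised CHMP1B, a subunit of the membrane scission complex ESCRT-III, from 8.31 ± 0.19 to 9.20 ± 0.20 (SD, n = 3 each), a change of 0.89 (SE 0.17, adjusted p = 0.0361). CPEB3 (0.86), the pseudogene VNN3P (0.82), TMEM132D (0.76), the palmitoyltransferase ZDHHC17 (0.71) and LINC00491 (0.68) also rose. RPL7AP10 (-0.86), WAC (-0.63), the cell cycle transcription factor E2F3 (-0.62), SAC3D1 (-0.61), BTBD1 (-0.59) and the mitochondrial magnesium channel MRS2 (-0.58) fell. In all, 40 probe sets were called, 15 higher and 25 lower, and 16 and 6 after quantile normalization, which ended the calls of RPL7AP10, E2F3 and SAC3D1. Leaving out 1 of the 6 arrays gave fewer in each case, from 1 (without estradiol 1) to 24 (without replicate 3 of estradiol with 4OHT). Leaving out the 3 sensitive arrays gave 307, including the 40. Of 21 G1/S and replication genes 20 had a negative change and 0 were called (8 lower adjusted over the list alone), with a median of -0.23 and an adjusted p of 2.68e-05 (adjusted p = 0.799 with an estimated correlation). Among its members were E2F2 (-0.60) and CDC25A (-0.69), which did not pass the test singly. The index genes did not pass the test, with changes from -0.67 for CCND1 (adjusted p = 0.1) to 0.09 for GREB1. HSPB8 had a value of -0.22 and MYC of -0.16. All 3 resistant arrays with both compounds ran at a station of their own, so that treatment and station cannot be told apart within this and the following resistant comparison. For the following one, 70 of 70 probe sets called for estradiol alone changed the same way, although another pair of stations was compared.

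The clone difference of that effect covered 67 probe sets, 8 higher and 59 lower in the resistant clone, and 0 and 2 after quantile normalization. Leaving out 1 of the 12 arrays gave 0 (without resistant estradiol 1, among others) to 274 (without sensitive estradiol 3), and a block for the replicate number gave 3. The difference was positive for ADO (1.20), the actin-severing protein CFL2 (0.96), KIRREL3-AS3 (0.88), LINC00491 (0.83) and ZSCAN26 (0.75). Their means rose in the resistant and fell in the sensitive clone (CFL2 from 5.90 to 6.35 and from 6.25 to 5.74). Negative differences were those of SOX2 (-1.40), the phosphoinositide 3-kinase subunit PIK3R3 (-1.02), TWIST1 (-1.0), IRF2BPL (-0.99) and ITPRIPL2 (-0.98), whose means fell in the resistant and rose in the sensitive clone. All 10 had an adjusted p of 0.0459. These 10 calls ended after quantile normalization. Estrogen-induced genes had a median difference of 0.41 with 0 of 32 called (3 adjusted over the list alone, adjusted p = 9.61e-08, and adjusted p = 0.565 with an estimated correlation), and ribosome biogenesis genes of 0.32 with 0 of 17 called on either count (adjusted p = 9.7e-07, and adjusted p = 0.565 with an estimated correlation). Estrogen-repressed genes had a median of -0.48 with 0 of 18 called (6 lower adjusted over the list alone, adjusted p = 0.00541, and adjusted p = 0.565 with an estimated correlation), and mitosis genes of -0.32 with 0 of 20 called (2 lower adjusted over the list alone, adjusted p = 0.00239, and adjusted p = 0.565 with an estimated correlation). Of the index genes, GREB1 had a difference of 1.72 (SE 0.48, adjusted p = 0.0897) and MYC of 1.43 (SE 0.51, adjusted p = 0.163). Without the 3 arrays 980 probe sets differed, including the 67, with 18 of 32 estrogen-induced genes called higher (adjusted p = 0.00471 with an estimated correlation), 5 of 17 ribosome biogenesis genes (adjusted p = 0.000724 with an estimated correlation) and GREB1 at 2.10.

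Estradiol on top of 4OHT asks which genes estradiol still changed while 4OHT was present, and whether the clones differed in this. In the resistant clone estradiol with 4OHT raised IGFBP4 from 6.28 ± 0.36 to 8.55 ± 0.53 (SD, n = 3 each), a change of 2.27 (SE 0.37, adjusted p = 0.0035). TSKU rose by 1.66, SIAH2 by 1.60, the galactosyltransferase B4GALT1 by 1.39, HSPB8 by 1.26, KCNK6 by 1.25 and TIPARP by 0.59. FOXO6 fell (-1.34), as did the helix-loop-helix inhibitors ID2 (-1.08) and ID1 (-0.90), NAV2-AS4 (-0.93), CRIM1 (-0.90), MMP16 (-0.82), TWIST1 (-0.61), the tight junction gene CLDN4 (-0.59) and GATA3 (-0.49). In all, 258 probe sets were called, 75 higher and 183 lower, and 108 and 92 after quantile normalization, which ended the calls of MMP16 and TWIST1. Estrogen-induced genes had a median of 0.49, and 4 of 32 were called higher and 0 lower (14 adjusted over the list alone): SIAH2, IGFBP4, HSPB8 and KRT13 (0.92). The list had an adjusted p of 2.75e-15 (adjusted p = 0.814 with an estimated correlation). Without the 3 sensitive arrays 17 of 32 were called and the list passed with an estimated correlation (adjusted p = 0.0147). TFF1 (0.97, adjusted p = 0.132), MYC (0.44), CCND1 (0.25), PGR (0.19), GREB1 (0.11), CXCL12 (0.10) and ESR1 (-0.16) did not pass the test. Without the 3 sensitive arrays, which lowers the spread in the shared model, 770 probe sets were called, including the 258. Leaving out 1 of the 6 resistant arrays gave 30 to 217, lowest without replicate 1 of estradiol with 4OHT.

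**Figure D1:**
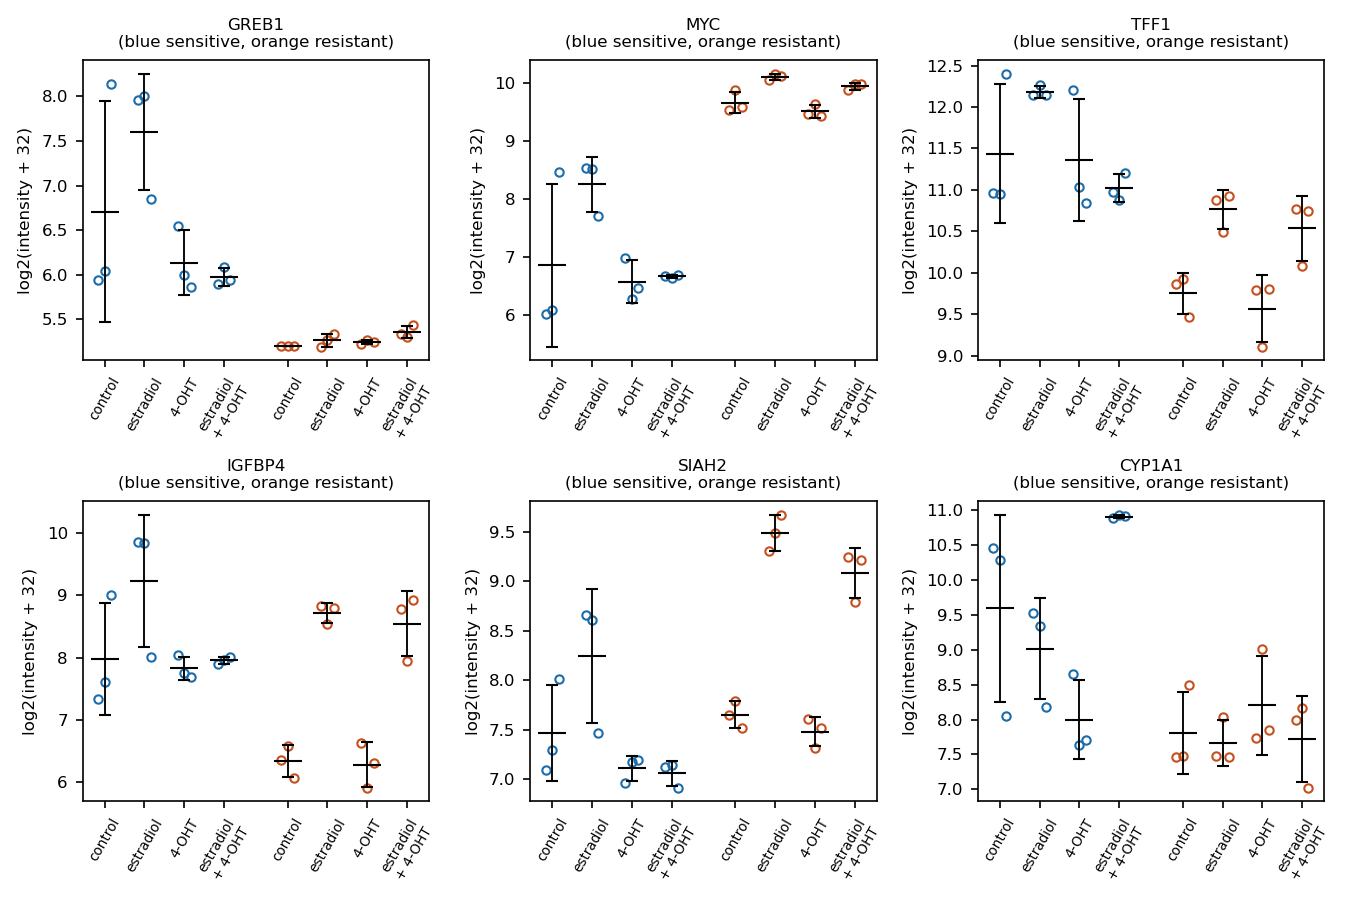
Log2(intensity + 32) of 6 genes on each array (points), with the mean and SD of the 3 arrays of a group (bars), for the 4 treatments of the sensitive (blue) and the resistant clone (orange). IGFBP4 stood at 8.72 with estradiol and 8.55 with estradiol and 4OHT in the resistant clone, against 6.33 in its control. Sensitive CYP1A1 stood at 10.91 with both compounds and 8.0 with 4OHT alone, and sensitive control 3 stands apart from the other controls for GREB1, MYC and TFF1.

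In the sensitive clone estradiol on top of 4OHT raised CYP1A1, a cytochrome P450 and standard target of the aryl hydrocarbon receptor (gene identifier 1543, chromosome 15), from 8.0 ± 0.57 to 10.91 ± 0.02 (SD, n = 3 each), a change of 2.91 (SE 0.46, adjusted p = 0.0115). CYP1B1 rose by 1.58, the decapping factor EDC3 by 0.67 and CABLES1 by 0.53, the latter pair no longer called after quantile normalization. The aryl hydrocarbon receptor list, 7 genes with 2 called (5 adjusted over the list alone), had a median of 0.28 and an adjusted p of 6.72e-07, and it remained called with an estimated correlation (adjusted p = 0.0264, and adjusted p = 0.000823 without the 3 arrays). Sterol synthesis genes had a median of -0.20 with 0 of 15 called on either count (adjusted p = 0.00227, and adjusted p = 0.666 with an estimated correlation), and mitosis genes of 0.16 with 0 of 20 called (2 adjusted over the list alone, adjusted p = 0.0352, and adjusted p = 0.666 with an estimated correlation). Both of these calls ended without the 3 arrays. In all, 14 probe sets were called, 10 higher and 4 lower, and 8 without the 3 arrays. Leaving out 1 of the 6 arrays gave 0 (without 4OHT 2, among others) to 4 (without 4OHT 1). The index genes did not pass the test, with changes from -0.34 for TFF1 to 0.29 for ESR1. HSPB8 had a value of -0.19 and GREB1 of -0.16. Within station 6, with 2 arrays of each group, 14 of 14 changed the same way, with a median ratio of 1.01 to their change over all arrays, and CYP1A1 differed by 3.23. Here too the arrays are among those that gave the calls, which favours agreement. With a fixed station block 5 probe sets were called, CYP1A1 no longer among them at a change of 3.23.

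The test of the clone difference of this effect called 459 probe sets, 78 higher and 381 lower in the resistant clone, and 92 and 77 after quantile normalization, which ended the calls of CCNG2 and BUB1. Leaving out 1 of the 12 arrays gave 61 (without resistant 4OHT 1) to 801 (without sensitive 4OHT 3), and 71 without sensitive 4OHT 1. The difference was 2.14 for IGFBP4 (SE 0.52, adjusted p = 0.042) and 1.65 for SIAH2 (SE 0.32, adjusted p = 0.0192). It was also positive for the bradykinin receptor BDKRB2 (1.37), ADRA2A (1.13) and FGFBP3 (1.06). The means of these 3 fell in the sensitive clone, from 5.83 to 5.31 for BDKRB2, 5.29 to 5.23 for ADRA2A and 5.68 to 5.34 for FGFBP3, all at 26.9 intensity units or less. The difference was negative for CYP1A1 (-3.39), CYP1B1 (-1.76), FOXO6 (-1.64), ID2 (-1.64), the cell cycle inhibitor CCNG2 (-1.40), CLDN4 (-0.80), the mitotic genes BUB1 (-0.69) and KIF11 (-0.67), and GATA3 (-0.57). The difference of HSPB8 was 1.45 (SE 0.38, adjusted p = 0.0552), that of TFF1 1.31 (SE 0.43, adjusted p = 0.107), that of MYC 0.34 and that of ESR1 -0.45 (SE 0.12, adjusted p = 0.059), none past the test. Estrogen-induced genes had a median difference of 0.33, with 2 of 32 called higher (5 adjusted over the list alone, adjusted p = 6.22e-08, and adjusted p = 0.455 with an estimated correlation). Without the 3 sensitive arrays 400 probe sets were called, 292 of them shared, with HSPB8 now called at 1.32. The study's limits, a 90% confidence interval beyond 1.1-fold, were applied to the model's interval on log2(value + 32). With them 1717 probe sets met the criterion in the resistant and 921 in the sensitive clone, 13 in both with the same sign. Of the 1637 that met it in the resistant clone alone, 264 had a clone difference past the adjusted test.

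Camera called 7 further lists for the clone difference of estradiol on top of 4OHT, each of which lost its call on leaving out 1 array or another. Mitosis genes had a median of -0.28 with 2 of 20 called lower (5 adjusted over the list alone, adjusted p = 0.0147, and adjusted p = 0.455 with an estimated correlation). At an adjusted p of 0.0492 each stood estrogen-repressed genes (median -0.35, 1 of 18 lower, 6 adjusted over the list alone), luminal markers (-0.22, 3 of 17 lower, 6 adjusted over the list alone), aryl hydrocarbon receptor targets (-0.31, 2 of 7 lower, 3 adjusted over the list alone), sterol synthesis (0.10, 0 of 15), interferon (0.072, 0 of 21) and ribosome biogenesis genes (0.085, 0 of 17), the last 3 with 0 adjusted over the list alone. With an estimated correlation their adjusted p was 0.663, 0.455, 0.455, 0.804, 0.455 and 0.804, in the same order. Without the 3 sensitive arrays the calls of sterol synthesis (median -0.053, adjusted p = 0.757), ribosome biogenesis (median -0.011, adjusted p = 0.757) and luminal markers (median -0.21, adjusted p = 0.0637) ended, the first 2 with medians of the opposite sign.

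**Figure D2:**
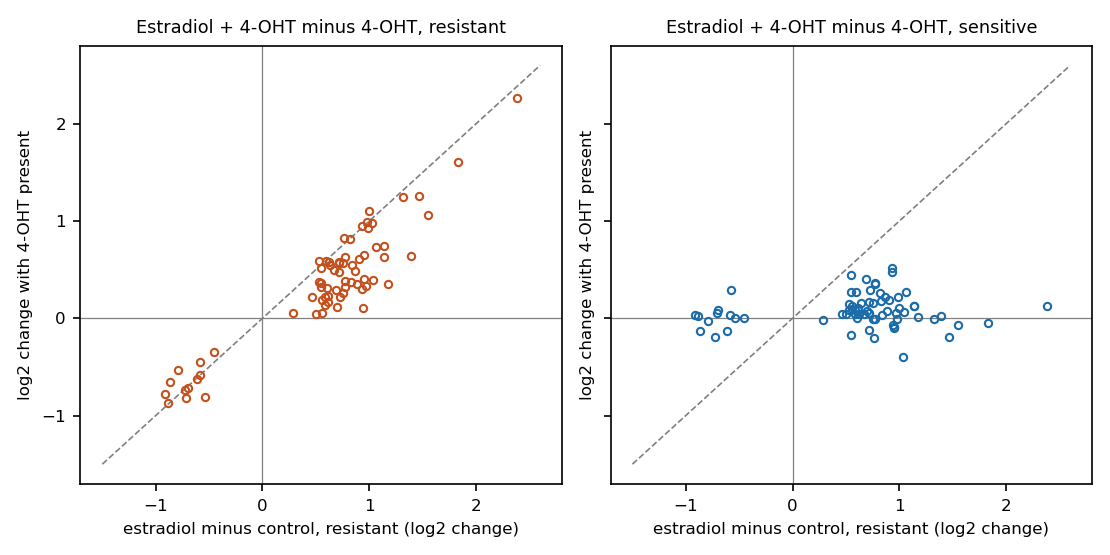
Log2 change with estradiol on top of 4OHT (vertical axis) of the 70 probe sets called for estradiol alone in the resistant clone, against their change with estradiol alone in the resistant clone (horizontal axis), in the resistant (left) and the sensitive clone (right). The dashed line marks equal change. In the resistant clone 70 of 70 had the same sign with a median ratio of 0.687, and in the sensitive clone 47 of 70 with a median ratio of 0.0827.

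The estrogen response score puts the response of each array on 1 scale per clone. The resistant clone was scored on the 42 probe sets called for estradiol in the sensitive clone. In that comparison treatment and batch cannot be told apart, and a model of only the groups compared called 0. No listed estrogen-induced gene was called there over all probe sets. In the resistant clone it was 0.04 ± 0.04 in control, 0.38 ± 0.01 with estradiol, -0.06 ± 0.05 with 4OHT and 0.28 ± 0.09 with both (SD, n = 3 each). Estradiol thus differed by 0.34 from control (SE 0.03, exact permutation p = 0.1, the smallest possible) and by 0.34 on top of 4OHT (SE 0.06, exact p = 0.1). Within station 2 the difference from control was 0.367 with 2 arrays of each group. In the sensitive clone the score was -0.99 ± 0.28 in control, -0.34 ± 0.41 with estradiol, -0.95 ± 0.02 with 4OHT and -0.86 ± 0.09 with both. Estradiol differed by 0.65 from control (SE 0.28, exact p = 0.2) and by 0.09 on top of 4OHT (SE 0.05, exact p = 0.1), and by 0.0494 within station 6. Leaving out 1 array also changes the probe sets scored. Without sensitive estradiol 1 or 2 none was called, so that the resistant clone had no score. Estradiol alone then gave in the resistant clone 0.0045 (without sensitive control 2, on 1 probe set) to 0.50 (without sensitive control 1), and estradiol on top of 4OHT 0.097 to 0.47 without the same arrays. For the sensitive clone estradiol alone gave 0.27 (without resistant control 2) to 1.03 (without sensitive control 3), and estradiol on top of 4OHT -0.046 (without sensitive control 3) to 0.13 (without sensitive estradiol 1). The clones were scored on different probe sets, so that their scales differ and no difference between the clones is taken from these scores.

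**Figure D3:**
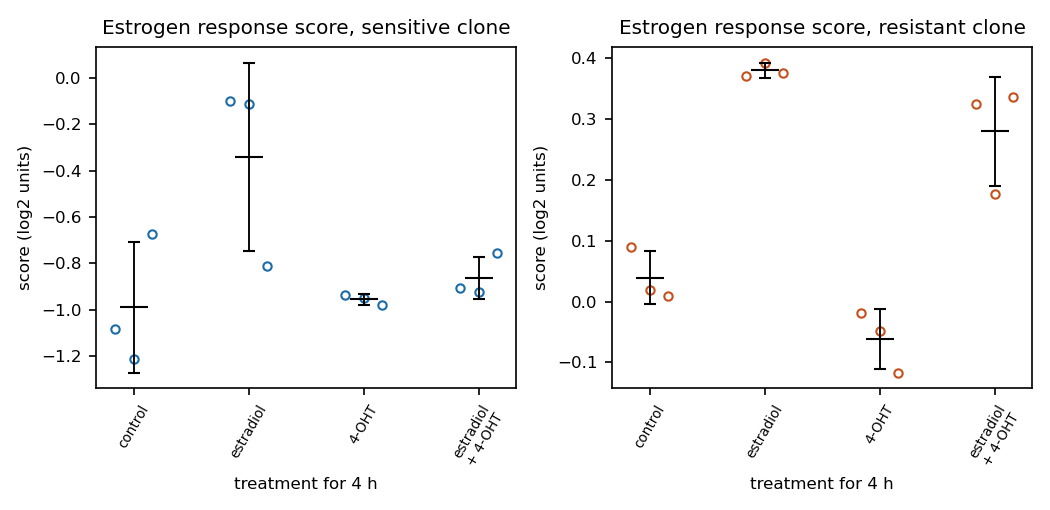
Estrogen response score in log2 units on each array (points), with the mean and SD of the 3 arrays of a group (bars), by treatment in the sensitive (left) and the resistant clone (right), each scored on the probe sets called for estradiol in the other clone. In the resistant clone the scores with estradiol and 4OHT (mean 0.28) lay above those with 4OHT alone (-0.06), and in the sensitive clone the means were -0.86 and -0.95.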

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

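The tests of the explanations weighed in this part were chosen after the results were seen, except the counts of other splits of the arrays, which were planned. The first pattern weighed is that 3 sensitive arrays stood apart from their groups. The positions of the arrays argue against an exchange of control 3 and estradiol 3 as the only cause. On a scale from control 1 and 2 (0) to estradiol 1 and 2 (1), 26 estrogen-induced genes placed estradiol 3 at a median of 0.318 (quartiles 0.151 to 0.440). They placed control 3 at 0.651 (0.558 to 0.866). These genes were picked for a clear difference between the arrays that set the ends, which draws other arrays inward. How far was not tested, so that a plain exchange is not excluded. Station or operator is excluded as the cause for control 3 and estradiol 3, since control 3 lay 0.406 and estradiol 3 lay 0.697 score units from the nearest array of the same group and station, where the largest SD of the other groups was 0.0911, but for 4OHT 1 station cannot be told apart from its deviation, since no other array of its group ran at its station (log2 correlation with these at most 0.980, and 0.982 between them). An exchange together with another difference may remain, since exchanging these arrays called 522 probe sets against 42, and so may a culture difference shared by the arrays, since the deviations of control 3 and 4OHT 1 correlated at 0.290 (highest of 84 other pairs 0.183), though estradiol 3 correlated at only 0.0429 with control 3 and 0.171 with 4OHT 1, and the values given for either would also follow from other causes. The design gives no group for these arrays, so no biological explanation was tested.

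The second pattern is the response to estradiol on top of 4OHT, which differed between the clones in 459 probe sets, found by a test of the difference itself. Of the 3 sensitive arrays that stood apart only 4OHT 1 enters this comparison. Without it the median difference went from 0.806 (median SE 0.184) to 0.777 (0.195) for the 78 called higher. For the 381 called lower it went from -0.694 (0.158) to -0.654 (0.166). With smaller differences and larger SE only 13 and 56 of them were still called. The probe sets were called with 4OHT 1 in the model, and the arrays that remain also gave the calls. Both favour a kept size, so that these medians cannot exclude 4OHT 1 as a cause. Replicate 3 of sensitive estradiol with 4OHT also enters and was not weighed in this way. It correlated at 0.980 and 0.978 with its replicates (0.987 between these) and had the highest GAPDH 3' to 5' ratio (0.585). Station is excluded as the cause of the direction for the probe sets called for estradiol alone in the resistant clone. Of these, 70 of 70 changed the same way on top of 4OHT, where arrays of another pair of stations were compared. The sign says nothing on the size (median ratio 0.687), so that a part of station in the size is not excluded. For the other probe sets treatment and station cannot be told apart, since all resistant arrays with both compounds ran at 1 station. These include most of the 183 called lower on top of 4OHT in that clone, and TSKU, B4GALT1, BDKRB2 and FGFBP3. Distribution differences between arrays are excluded as the whole cause for the mean of the 42 probe sets called for estradiol in the sensitive clone. Those were called on other arrays, and after quantile normalization their change differed between the clones by 0.444 (SE 0.140). Of the 78 probe sets called higher 61 were then still called, and 77 of the 381 called lower. The median difference of the latter went from -0.694 to -0.604 (median SE 0.153). The median of all probe sets shifted from -0.0673 to -0.0112. The 78 and the 381 were called on these same arrays, which favours a kept size, so that for them distribution differences are not excluded. A difference between the clones themselves stays open as a hypothesis for those of the 70 that changed less in the sensitive clone. Examples on top of 4OHT are IGFBP4 (2.27 in the resistant against 0.13 in the sensitive clone), SIAH2 (1.60 against -0.05) and, falling, SYTL2 (-0.82 against 0.05). Some of the 70 did not change less there, such as ADCY9 (0.21 against 0.29). For probe sets outside the 70 a clone difference cannot be told apart from station.

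The third pattern is CYP1A1 and CYP1B1, which estradiol on top of 4OHT raised in the sensitive clone with clone differences of -3.39 and -1.76. Station is excluded as the cause of the CYP1A1 rise of 2.91, which was 3.23 within station 6. With a fixed station block CYP1A1 kept this size but lost its call (SD of 3 arrays 0.57 and 0.02 in the groups compared), a model that estimates more terms from the same arrays. The 3 arrays that stood apart are excluded as well, since CYP1A1 rose by 3.24 without them. No biological explanation was tested.

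Other differences between the clones were also found by a test of the difference itself (resistant minus sensitive, log2). For estradiol alone 3 probe sets differed, with RETREG1 at 1.25 and ADRA2A, weakly expressed in the sensitive clone with 4OHT, at 1.33. For 4OHT on top of estradiol 67 differed: ADO (1.20), CFL2 (0.96), KIRREL3-AS3 (0.88), LINC00491 (0.83), ZSCAN26 (0.75), SOX2 (-1.40), PIK3R3 (-1.02), TWIST1 (-1.0), IRF2BPL (-0.99) and ITPRIPL2 (-0.98). For estradiol on top of 4OHT the named genes were IGFBP4 (2.14), SIAH2 (1.65), BDKRB2 (1.37), ADRA2A (1.13), FGFBP3 (1.06), FOXO6 (-1.64), ID2 (-1.64), CCNG2 (-1.40), CLDN4 (-0.80), BUB1 (-0.69), KIF11 (-0.67) and GATA3 (-0.57).

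Gene lists whose clone difference passed camera had these medians. Ribosome biogenesis stood at -0.23 for estradiol alone, 0.32 for 4OHT on top of estradiol and 0.085 for estradiol on top of 4OHT. Aryl hydrocarbon receptor targets stood at 0.41 for 4OHT alone and -0.31 for estradiol on top of 4OHT. Estrogen-induced genes stood at 0.41 for 4OHT on top of estradiol and 0.33 for estradiol on top of 4OHT, estrogen-repressed genes at -0.48 and -0.35, and mitosis genes at -0.32 and -0.28. For estradiol on top of 4OHT sterol synthesis stood at 0.10, interferon at 0.072 and luminal markers at -0.22. None of these clone differences passed with an estimated correlation (adjusted p from 0.353 to 0.982). Without the 3 sensitive arrays 4 did: ribosome biogenesis for estradiol alone (adjusted p = 5.79e-05) and for 4OHT on top of estradiol (0.000724), estrogen-induced genes for 4OHT on top of estradiol (0.00471) and aryl hydrocarbon receptor targets for 4OHT alone (0.00306), and so did estrogen-induced genes for estradiol alone (0.0402), lower in the resistant clone, which camera had not called with all arrays. For estradiol on top of 4OHT the medians of sterol synthesis (-0.053) and ribosome biogenesis (-0.011) had the opposite sign without the 3 sensitive arrays.

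Other splits of the same arrays were counted. Each number of splits includes the real one. Splits of 3 arrays against 3 number 10, too few for a share under 0.05. The real value and the highest of the other splits were 42 and 522 for estradiol in the sensitive clone (2 of 10 splits gave as many), 70 and 0 in the resistant clone (1 of 10), and 0 and 175 for 4OHT in the sensitive clone (10 of 10). They were 1 and 1 for 4OHT in the resistant clone (2 of 10), 49 and 11 for 4OHT on top of estradiol in the sensitive clone (1 of 10) and 40 and 1 in the resistant clone (1 of 10). For estradiol on top of 4OHT they were 14 and 1 in the sensitive (1 of 10) and 258 and 0 in the resistant clone (1 of 10), and 6103 and 0 between the untreated clones (1 of 10). The split with 522 exchanges control 3 and estradiol 3, which points to a structure of the samples. Among 100 splits for each clone difference, the real one and 99 drawn, chance cannot be excluded for estradiol (3 against a highest of 819, with 11 of 100 as large). For 4OHT the values were 0 against 30, with 100 of 100. Every split reaches a real count of 0, so that for 4OHT here and in the sensitive clone the splits test nothing. The real split called the most for 4OHT on top of estradiol (67 against 52, with 1 of 100) and for estradiol on top of 4OHT (459 against 121, with 1 of 100). The drawn splits mix treatments within each clone, so that they also break up any treatment effect that the clones share. They therefore cannot decide whether the difference between the clones arose by chance.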

How the results depend on the processing

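The 147 calls of named genes gave 2500 combinations of a call and an alternative setting. Of these, 1835 kept their direction and call, 665 kept the direction and lost the call, and 0 reversed. Leaving out 1 array made up 1038 of them. The largest rises and falls within a clone or between the controls were chosen without overlap of the groups. Leaving out 1 array thus could not reverse these. Of 876 combinations of the 44 called gene lists with a setting, 675 kept the call, 201 lost it and 0 reversed, and 1 of 44 remained with an estimated correlation (17 of 44 with fry). Of 1699 combinations of the 95 index gene results not called with a setting, 73 gave a call. Counts moved more, and the cause was not tested unless said. Leaving out 1 array leaves 2 in its group. A fixed station block, possible for 4 of the 13 comparisons, ended 29 of 32 named calls there. The station as a random block gave a correlation within stations of -0.0694, which is negative and narrowed the test, but the group means absorb most of a station effect, so that it says nothing on how alike arrays of a station are. Of the values, 1.15% were exactly 1 and the median of all was 16.9, below the pseudocount of 32, so that changes of weakly expressed genes are understated.

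In the counts below, S stands for the sensitive clone, R for the resistant clone and D for their difference. With the 3 arrays left out, chosen after seeing the data, estradiol called 1720 (S), 305 (R) and 242 (D) probe sets, 4OHT 24 (S) and 8 (D), 4OHT on top of estradiol 911 (S), 307 (R) and 980 (D), and estradiol on top of 4OHT 8 (S) and 770 (R). The score then changed by 1.35 for estradiol, 0.24 for 4OHT and -1.07 for 4OHT on top of estradiol in S, and by -0.036 for 4OHT in R.

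With the study's limits applied to the model's 90% interval (beyond 1.1-fold), which adjusts for no multiple tests, the counts were 1618 (S), 735 (R) and 1159 (D) for estradiol, 849 (S), 263 (R) and 1123 (D) for 4OHT, 1349 (S), 1661 (R) and 3087 (D) for 4OHT on top of estradiol, and 921 (S), 1717 (R) and 3641 (D) for estradiol on top of 4OHT. A model of only the groups compared gave 0 (S), 275 (R) and 0 (D) for estradiol, 2 (R) for 4OHT, 137 (S), 109 (R) and 438 (D) for 4OHT on top of estradiol, and 1 (S) for estradiol on top of 4OHT.

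With a pseudocount of 100 the counts were 5 (D) for estradiol, 3 (R) and 3 (D) for 4OHT, and 75 (S), 68 (R) and 3 (D) for 4OHT on top of estradiol. The score in R changed by 0.22 for estradiol, -0.046 for 4OHT, 0.21 for estradiol on top of 4OHT and 0.16 for both against control. With a pseudocount of 8 the counts were 0 (R) for 4OHT and 8 (S) for estradiol on top of 4OHT, and the score changed by 0.41 for estradiol in R.

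Without a filter, which tests more probe sets, the counts were 3 (S) for 4OHT, 21 (S), 22 (R) and 2 (D) for 4OHT on top of estradiol, and 149 (R) and 217 (D) for estradiol on top of 4OHT, with a score change of 0.27 for estradiol in R. With the stricter filter they were 204 (S) for estradiol, 146 (S), 245 (R) and 491 (D) for 4OHT on top of estradiol, and 456 (R) and 1005 (D) for estradiol on top of 4OHT. The score in R then changed by 0.39 for estradiol and 0.31 for both against control, and the correlation of the estradiol changes between the clones was 0.366. Quantile normalization gave 23 (S), 22 (R) and 2 (D) for 4OHT on top of estradiol and 169 (D) for estradiol on top of 4OHT, with score changes in R of 0.26 for estradiol and -0.036 for 4OHT on top of estradiol.

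A block for the replicate number, for which no pairing was seen, gave 10 (S) for estradiol, 2 (R) and 2 (D) for 4OHT, 2 (S) and 3 (D) for 4OHT on top of estradiol, 9 (S) for estradiol on top of 4OHT and 3970 between the untreated clones. The station as a fixed batch block gave 5 (R) for estradiol, 0 (R) for 4OHT, 5 (S) for 4OHT on top of estradiol and 5 (S) for estradiol on top of 4OHT. The station as a random batch block gave 815 (S) for estradiol, 3 (D) for 4OHT, 432 (R) and 969 (D) for 4OHT on top of estradiol, and 894 (R) and 1103 (D) for estradiol on top of 4OHT.

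Leaving out each array in turn gave 0 to 1279 (S), 16 to 48 (R) and 3 to 40 (D) for estradiol, 0 to 16 (S), 0 to 1 (R) and 0 to 1 (D) for 4OHT, 0 to 364 (S), 1 to 24 (R) and 0 to 274 (D) for 4OHT on top of estradiol, 0 to 4 (S), 30 to 217 (R) and 61 to 801 (D) for estradiol on top of 4OHT, and 4737 to 6267 between the untreated clones. The highest counts for estradiol (S, D) and 4OHT (S) came without control 3, and those for 4OHT on top of estradiol (S, D) without estradiol 3. The lowest came without estradiol 1 for estradiol and 4OHT on top of estradiol in S. Correlations ran from 0.150 to 0.267 between the clones and, for 4OHT with estradiol, from 0.456 to 0.714 (S) and 0.368 to 0.530 (R). Score changes in S ran from 0.27 to 1.03 for estradiol, -0.17 to 0.35 for 4OHT, -0.91 to -0.35 for 4OHT on top of estradiol, -0.046 to 0.13 for estradiol on top of 4OHT and -0.18 to 0.31 for both against control. In R, where leaving out sensitive estradiol 1 or 2 left no probe set to score and 22 of 24 omissions gave a score, they ran from 0.0045 (on 1 probe set) to 0.50 for estradiol, -0.13 to 0.33 for 4OHT, -0.11 to 0.30 for 4OHT on top of estradiol, 0.097 to 0.47 for estradiol on top of 4OHT and -0.038 to 0.80 for both against control, with most of these ends reached without sensitive control 1 or 2, which change the probe sets scored.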

Other observations

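The genes and the set of arrays in this part were chosen after their values were seen, and the adjusted p-values are from the limma model without sensitive control 3, estradiol 3 and 4OHT 1. In that model estradiol raised in the sensitive clone the prostaglandin E synthase gene PTGES by 2.30 on the log2 scale (SE 0.24, adjusted p = 7.11e-07), STC2 by 2.22, the receptor tyrosine kinase RET by 2.17, the amino acid transporter SLC7A5 by 1.93 and XBP1 by 1.77. It lowered WNT2B (-1.75), DDIT4 (-1.61) and TNFRSF11B (-1.52). The changes with 4OHT on top of estradiol were -2.02 for PTGES, -1.62 for RET, -1.48 for STC2, -1.43 for XBP1, -0.70 for SLC7A5, 1.49 for DDIT4, 1.29 for TNFRSF11B and 1.04 for WNT2B. Both comparisons share estradiol 1 and 2, which favours opposite signs for genes chosen by their estradiol change.

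In the same model the resistant clone had smaller rises with estradiol for PTGES (1.00), RET (0.92), STC2 (0.63), XBP1 (0.50) and SLC7A5 (0.48), with clone differences from -1.59 for STC2 to -1.25 for RET. A smaller rise there is favoured by the choice of the genes, which were picked for their rise on the sensitive arrays of the same clone difference. On top of 4OHT the changes in the resistant clone were 1.08 for PTGES, 0.94 for STC2, 0.53 for RET, 0.46 for XBP1 and 0.29 for SLC7A5 (adjusted p from 1.8e-06 to 0.0398). For the last 4 treatment and station cannot be told apart there, while another probe set of PTGES is among the 70 called for estradiol alone (1.03, and 0.98 on top of 4OHT), which changed the same way between other stations.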
